A study of Homo sapiens with 6 samples.

How the data were processed

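RNA sequencing values of 6 samples of the human cell line ARPE-19 were used, 3 controls and 3 treated with NaIO3 for 24 h. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was fragmented and copied from random primers, and the second strand was marked with dUTP, a strand-specific design. The submitters' processing notes name cutadapt, HISAT2 2.0.5, StringTie and the genome build hg19. How these were run is not given in the sources used here.

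The deposited table holds FPKM values per gene, with hg19 coordinates and symbols. No source names the unit. It was read from the form of the values, which are never negative, not whole and differ in sum between samples. Of 721 genes with a single transcript in GENCODE release 29, 99.3% had at most 6 decimals in every sample, against 0.6% of 11252 genes with several transcripts, as gene values combined from transcript FPKM would have. The filter that chose the 12028 genes is not given in the sources used here. A total of 4 genes were listed at 0 in every sample. Low values times transcript length were searched for a step that 1 read would give. In the 50 lowest values per sample, the best step made 34 to 48% of values whole within 0.1 of a read, against a median of 36% in 200 sets of random values. Control replicate 3, at 48%, lay above the highest random set (44%), and NaIO3 replicate 1, at 44%, was matched by 2% of the sets, while the other 4 samples stood at 34 to 36%. No step made most values whole in any sample. Whole reads were therefore not recovered, the sequencing depth is unknown, and no counting intervals are given.

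Values were transformed to log2(FPKM + 1) without further normalization. Genes with a mean FPKM of at least 0.5 over all samples were tested (11590, leaving 438 untested). NaIO3 was compared with control in limma 3.58.1 (R 4.3.3) with a moderated variance that follows the mean level, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. All adjusted p-values of single genes come from this two-sided limma test. Gene lists were written before the data were examined, and those with at least 5 tested members were tested with camera with a preset correlation of 0.01, adjusted over the 26 lists. Camera with a correlation estimated from the samples and fry were alternatives. An exact permutation test of 3 against 3 samples cannot go below 0.1 and was not used.

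Genes were named by a rule set before the data were examined. It took the 5 largest increases and 5 largest decreases among genes past the threshold, with at least 5 FPKM in the higher group and no overlap between groups. It also took the 2 most changed members of each of the 10 lists with the smallest camera p, the member with the smallest p of each other list, and 10 fixed genes, among them HMOX1, NQO1, TXNRD1, SLC7A11, CDKN1A, GDF15, VEGFA, RPE65 and BEST1. Some genes that the rule took are not reported here. XIST and Y-linked genes were left out.

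Alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum mean of 5 FPKM, median centring, quantile normalization, rescaling to a common sum, no variance trend, a robust trend, the replicate number as a block, and each sample left out in turn. Chosen after the data were seen were rescaling without the mitochondrially encoded transcripts, and removal of trends with transcript length, GC content and mean level from each sample by loess with a span of 0.5. Lengths and GC content came from GENCODE release 29, matched by gene identifier for 99.5% of genes, and none of its coordinates were used. Lists added after the data were seen cover fatty acid synthesis, LXR targets, proteasome subunits, ERK pathway feedback and output genes, YAP and TEAD targets and keratins.

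The limma and camera steps were first tested on simulated data for the comparison of NaIO3 with control, with 11590 genes drawn from the real means and spreads and 200 of them changed. The test recovered 4% of genes changed 1.2-fold, 66% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, with 8 false calls among 137, and it called 0 genes when none was changed. Camera called the 1 shifted list and 0 lists when none was shifted. Simulated genes were independent of each other, unlike real ones. Figures were drawn with matplotlib in Python.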

Results

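Transcript levels were measured by RNA sequencing in ARPE-19 cells, a human cell line derived from the retinal pigment epithelium (RPE), the pigmented layer that supports the photoreceptors. Cells treated for 24 h with sodium iodate (NaIO3), an oxidant used experimentally to injure the RPE, were compared with control cells, with 3 samples in each group. The table gives FPKM (fragments scaled by transcript length and sequencing depth) for 12028 protein-coding genes, and 11590 genes with a mean of at least 0.5 FPKM were tested. FPKM summed to 198345, 196528 and 198329 in control replicates 1 to 3 and to 195706, 195023 and 182099 in NaIO3 replicates 1 to 3. The number of reads behind these values is unknown, so no counting interval is given. Fold changes were computed on the log2(FPKM + 1) scale and understate the change of genes with low levels. Nothing in the sample descriptions says whether the 3 samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

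The comparison asked how the transcriptome of the cells differed after NaIO3. Stress-response transcripts were higher in the treated cells, led by HSPA6 and HMOX1, along with targets of the transcription factors NRF2 and ATF4, heat shock proteins and immediate early genes. Transcripts of cholesterol synthesis, DNA replication and the contractile cytoskeleton were lower. The list calls for ATF4 targets, immediate early genes and the contractile cytoskeleton were lost when the correlation between genes was estimated (adjusted p = 0.14 with an estimated correlation for each). In total 5096 genes passed the limma test at an adjusted p of 0.05, of which 2955 were higher and 2141 lower with NaIO3, and 331 of them changed at least 2-fold (142 up, 189 down). The number of calls of at least 2-fold depends on the pseudocount, with 442 at 0.5 and 621 at 0.1. All 3 treated samples lay beyond all 3 control samples for 6536 genes (56.4% of those tested, against 10% by chance). Correlations of log2 values ran from 0.985 to 0.986 within the control group, from 0.980 to 0.984 within the NaIO3 group and from 0.946 to 0.952 between groups. The share of calls that were higher, 58.0%, was 43.8% after median centring of the samples, so which small changes passed depends on the scaling. Median centring gave 5084 calls, and 4370 were shared by both. The shared calls kept their direction, but centring shifts all log2 fold changes alike, so they could hardly reverse.

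Of 28 gene lists, 26 had at least 5 tested members, and 15 passed the camera test with a preset correlation of 0.01 (7 upwards, 8 downwards). With a correlation estimated from the data, 4 lists passed, namely cholesterol synthesis, DNA replication, NRF2 targets and heat shock proteins. The estimates ran as high as 0.93 for mitochondrially encoded transcripts and 0.53 for ribosomal proteins. They were below the preset 0.01 for interferon response genes (-0.0024), RPE markers (-0.049) and p53 targets (0.0093), whose calls were also lost. Cholesterol synthesis, with an estimate of 0.0084, also below the preset, went from an unadjusted camera p of 5.9e-17 to 0.0010. The test with an estimated correlation was thus stricter even where its correlation was not higher. A call lost with it does not by itself show that correlation between genes made the call. List members given as examples below that the rule for named genes did not take were chosen after their values were seen.

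**Figure D1:**
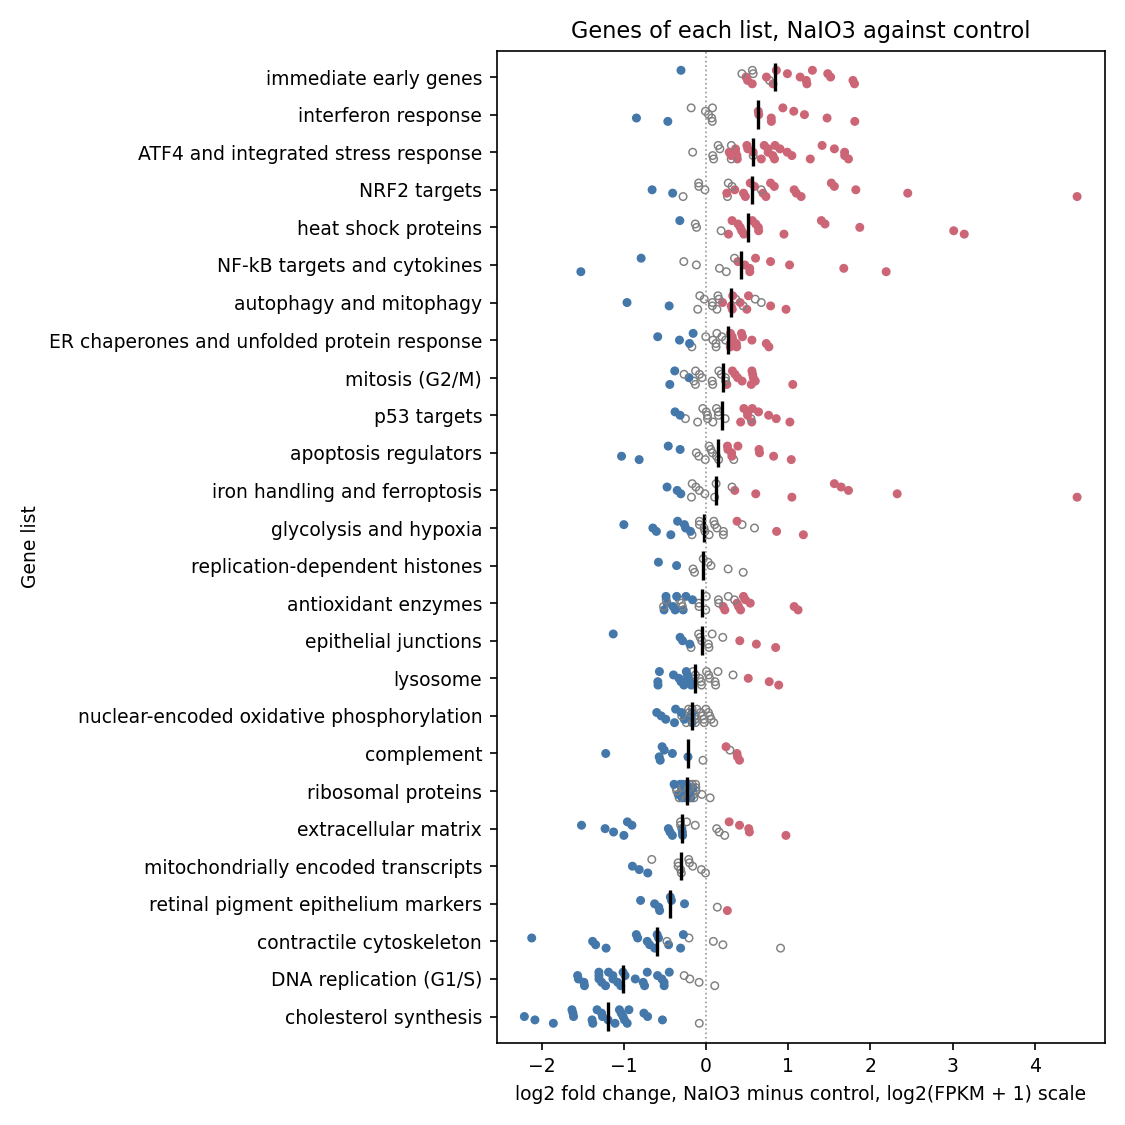
Log2 fold change (NaIO3 minus control, log2(FPKM + 1) scale, horizontal axis) of each tested member of the 26 tested lists (vertical axis), with 3 samples per group. Filled red and blue points are genes higher and lower with NaIO3 at an adjusted p below 0.05 (limma), open points did not pass, and black bars are list medians, which run from -1.19 for cholesterol synthesis to 0.83 for immediate early genes.

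NRF2 targets, the genes of the main antioxidant transcription programme, rose as a list. Of 28 tested members, 18 rose, 2 fell and 8 did not pass, and 20 passed when adjusted over the list alone. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1 (ENSG00000100292.16, chromosome 22, 35776354 to 35790207, hg19), went from 5.93 ± 0.97 to 157 ± 19.5 FPKM (SD, n = 3), a 26.5-fold difference in mean FPKM and a log2 fold change of 4.51 (SE 0.13, limma adjusted p = 1.3e-05). OSGIN1 rose 7.28-fold, from 2.497 ± 0.145 to 18.2 ± 1.46 FPKM. The cystine transporter gene SLC7A11 rose from 16.8 ± 1.26 to 51.3 ± 3.52 FPKM, the quinone reductase gene NQO1 from 71.6 ± 0.984 to 160.9 ± 8.47, and the thioredoxin reductase gene TXNRD1 from 216 ± 1.8 to 456 ± 28.8. The list had a median log2 fold change of 0.56, a camera adjusted p of 7.7e-06, and adjusted p = 0.049 with an estimated correlation. Antioxidant enzymes moved both ways, with 10 of 32 higher and 9 lower (20 past the threshold adjusted over the list alone). Their median was -0.05, their mean 0.03, and the list did not pass (camera adjusted p = 0.73). Among iron handling and ferroptosis genes, 8 of 19 rose and 3 fell (12 passed adjusted over the list alone; camera adjusted p = 0.14). Of the 4 metallothionein genes, too few for a list test, 3 rose, both over all genes and adjusted over the list alone, including MT1X, from 10.1 ± 0.626 to 32.8 ± 4.25 FPKM.

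**Figure D2:**
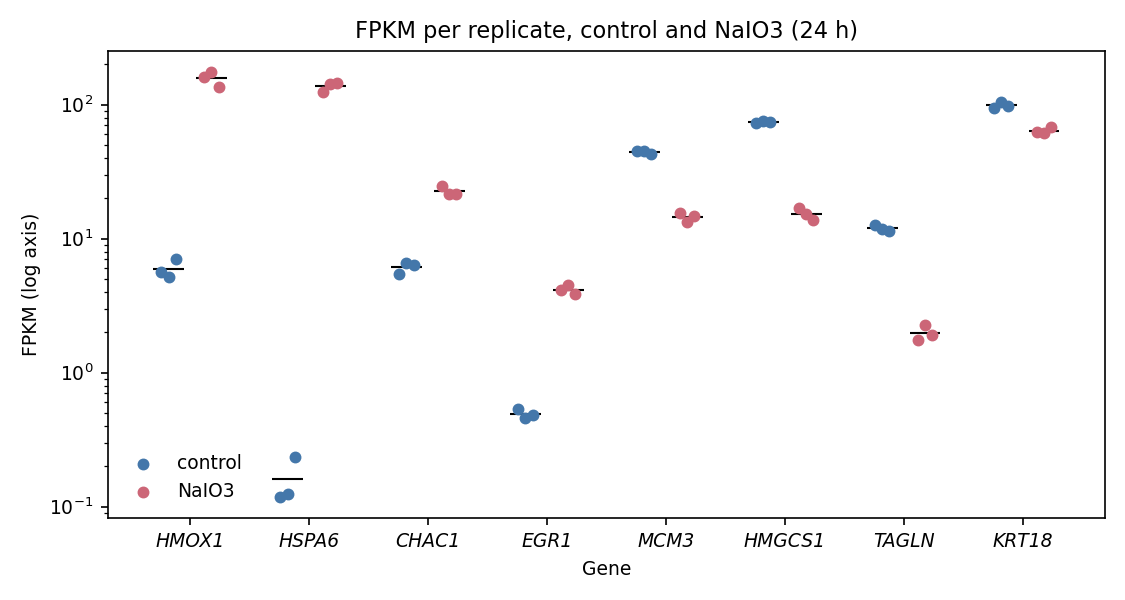
FPKM (log axis) of 8 genes in each of the 3 control and 3 NaIO3 samples; points are replicates and lines are group means. For every gene shown, the 3 treated samples lie beyond the 3 control samples, as for HMGCS1, with means of 74.4 FPKM in controls and 15.3 FPKM after NaIO3.

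Genes of the ATF4 programme, which is induced when translation initiation is restrained under stress, rose in 25 of 33 cases, and none fell. CHAC1 went from 6.13 ± 0.629 to 22.7 ± 1.9 FPKM and SESN2 from 17.0 ± 0.237 to 57.0 ± 5.02. The median log2 fold change was 0.57, and 27 members passed adjusted over the list alone. The camera adjusted p was 4.7e-10, with adjusted p = 0.14 with an estimated correlation. DDIT3, a widely used marker of this response, stood at 25.6 FPKM in controls and 22.6 after NaIO3 and did not pass. Heat shock proteins rose in 16 of 20 cases, and 1 fell (18 passed adjusted over the list alone; median 0.51, camera adjusted p = 1.2e-06, adjusted p = 0.049 with an estimated correlation). HSPA1A and HSPA1B rose from 52.4 ± 2.54 to 430.1 ± 31.3 and from 50.6 ± 3.08 to 455 ± 33.9 FPKM. These genes are near-identical copies, so how their reads were divided is uncertain. HSPB1 was the member that fell, by 0.32 on the log2 scale. HSPA6, a strictly inducible relative of HSPA1A that lies outside the list (ENSG00000173110.7, chromosome 1, 161494330 to 161496700, hg19), had the largest increase among the named genes, from 0.16 ± 0.066 to 137 ± 10.8 FPKM (log2 fold change 6.90, SE 0.08, limma adjusted p = 2.7e-07). Among chaperones and unfolded protein response genes of the endoplasmic reticulum, 12 of 24 rose and 4 fell (16 adjusted over the list alone), with DNAJB9 rising from 7.01 ± 0.389 to 12.3 ± 0.817 FPKM and the list not passing (camera adjusted p = 0.088), although it passed with quantile normalization (adjusted p = 0.049).

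Immediate early genes, which respond within minutes to growth factor and stress signals, rose in 15 of 20 cases, and 1 fell (17 passed adjusted over the list alone). The phosphatase gene DUSP6 went from 1.94 ± 0.329 to 9.28 ± 1.11 FPKM and the transcription factor gene EGR1 from 0.492 ± 0.0424 to 4.16 ± 0.353. The list median was 0.83 and its camera adjusted p 3.3e-07, with adjusted p = 0.14 with an estimated correlation. NF-kB targets and cytokines rose in 9 of 16 cases and fell in 2 (11 adjusted over the list alone). Their median was 0.43 (camera adjusted p = 0.049, adjusted p = 0.23 with an estimated correlation). CXCL8, which encodes the neutrophil attractant interleukin 8, rose from 27.9 ± 1.5 to 132 ± 22.4 FPKM, whereas CCL2, the gene of a monocyte attractant, fell from 11.9 to 3.53. The NF-kB list no longer passed without control replicate 1 (adjusted p = 0.051), control replicate 2 (0.053), NaIO3 replicate 1 (0.058) or NaIO3 replicate 3 (0.064). In that order its medians were 0.45, 0.40, 0.46 and 0.40. Among members with a mean of at least 5 FPKM its median was 0.02, with camera pointing downwards (adjusted p = 0.95). Interferon response genes rose in 9 of 17 cases and fell in 2 (11 adjusted over the list alone; median 0.63, camera adjusted p = 0.021, adjusted p = 0.14 with an estimated correlation). IFIT2 rose from 2.88 ± 0.188 to 12.6 ± 0.821 FPKM, and the 2 that fell were IRF9 and OAS3. Of 13 complement genes, 4 rose and 7 fell, 11 of them past the threshold adjusted over the list alone as well, and the list did not pass (camera adjusted p = 0.091). C3, the central complement component, fell from 7.73 ± 0.237 to 2.75 ± 0.255 FPKM.

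Cholesterol synthesis transcripts fell in 22 of 23 cases, and none rose (22 adjusted over the list alone). The median log2 fold change was -1.19, the camera adjusted p 1.5e-15, with adjusted p = 0.027 with an estimated correlation. HMGCS1, which encodes an early enzyme of the pathway (ENSG00000112972.14, chromosome 5, 43289497 to 43313614, hg19), fell from 74.4 ± 1.24 to 15.3 ± 1.47 FPKM (log2 fold change -2.21, SE 0.07, limma adjusted p = 2.1e-05). MSMO1 fell from 154 ± 4.91 to 35.9 ± 4.79 FPKM. PMVK, at 23.9 and 22.6 FPKM, was the 1 member that did not pass.

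DNA replication and G1/S transcripts fell in 25 of 29 cases, and none rose (27 adjusted over the list alone; median -1.01, camera adjusted p = 3.9e-15, adjusted p = 0.049 with an estimated correlation). E2F1, a transcription factor of S-phase entry, fell from 23.5 ± 1.49 to 7.30 ± 0.456 FPKM. MCM3, a subunit of the replicative helicase (ENSG00000112118.18, chromosome 6, 52128807 to 52149679, hg19), fell from 44.5 ± 1.39 to 14.5 ± 1.18 (log2 fold change -1.55, SE 0.07, limma adjusted p = 3.9e-05). Among mitosis genes, 11 of 26 rose, including CCNB1 (cyclin B1) from 55.4 ± 0.851 to 82.5 ± 2.83 FPKM, and 3 fell (15 adjusted over the list alone). The mitosis list did not pass (median 0.21, camera adjusted p = 0.091). Of 9 replication-dependent histone genes, 2 fell, over all genes and adjusted over the list alone, one being HIST1H2BK (43.2 ± 3.72 to 28.5 ± 0.707 FPKM), and the list did not pass (camera adjusted p = 0.39). Targets of p53 rose in 10 of 24 cases and fell in 2 (12 adjusted over the list alone; median 0.19, camera adjusted p = 0.036, adjusted p = 0.20 with an estimated correlation). MDM2, the p53 ubiquitin ligase gene, rose from 8.06 ± 0.477 to 14.3 ± 0.143 FPKM. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 88.3 ± 2.3 to 122.9 ± 20.5 FPKM (limma adjusted p = 0.022). That call was lost on leaving out any single sample except NaIO3 replicate 3, with adjusted p from 0.053 to 0.067, and the p53 list call was lost without control replicate 3 (adjusted p = 0.059). Without control replicate 1 the p53 list median was 0.31.

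Genes of the contractile cytoskeleton list fell in 14 of 19 cases, and none rose past the threshold over all genes. Adjusted over the list alone 17 passed, 2 of them upwards (median -0.60, camera adjusted p = 9.7e-07, adjusted p = 0.14 with an estimated correlation). As written, the list also holds VIM and the transcription factor genes SRF, SNAI2, ZEB1 and ZEB2, so its counts are not of contractile genes alone. TAGLN (transgelin) went from 11.9 ± 0.635 to 1.98 ± 0.251 FPKM and the myosin light chain gene MYL9 from 34.3 ± 1.7 to 12.6 ± 1.13. Extracellular matrix genes fell in 12 of 24 cases and rose in 5 (18 adjusted over the list alone; median -0.29, camera adjusted p = 0.022, adjusted p = 0.34 with an estimated correlation). Fibronectin (FN1) fell from 35.8 ± 0.0556 to 14.7 ± 0.575 FPKM. Of the 24 RPE markers in the list, 11 were in the table and 9 were tested. RPE markers fell in 7 of these 9 cases, and 1 rose (8 adjusted over the list alone). Their median was -0.44 (camera adjusted p = 0.0060, adjusted p = 0.14 with an estimated correlation). The largest decreases in that list were those of KRT8 (87.2 ± 2.85 to 49.8 ± 1.24 FPKM) and KRT18 (98.9 ± 5.81 to 63.7 ± 3.85), keratins found in simple epithelia in general. BEST1, an RPE chloride channel gene, lay below the level for testing, at 0.238 ± 0.0499 and 0.297 ± 0.0972 FPKM, and RPE65 and GDF15 were not analysed here. Epithelial junction genes rose in 3 and fell in 4 of 15 cases (7 adjusted over the list alone; camera adjusted p = 0.73), with CLDN1 rising from 14.8 ± 0.69 to 27.5 ± 1.28 FPKM. Of the markers of other cell types, 2 could be tested. PDGFRB, a pericyte and fibroblast marker, fell from 5.92 ± 0.136 to 1.90 ± 0.123 FPKM, also past the threshold adjusted over the list alone, and the macrophage marker CD68 stood at 14.2 and 16.3 FPKM and did not pass.

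Autophagy and mitophagy genes rose in 9 of 23 cases and fell in 2 (11 adjusted over the list alone; camera adjusted p = 0.091). PINK1, a kinase of mitophagy, was one that fell, from 35.1 ± 0.122 to 17.6 ± 1.42 FPKM. Lysosomal genes fell in 12 and rose in 3 of 27 cases (15 adjusted over the list alone; camera adjusted p = 0.073), and CTSL (cathepsin L) rose from 32.9 ± 1.57 to 56.6 ± 1.47 FPKM. Apoptosis regulators rose in 9 and fell in 4 of 22 cases (13 adjusted over the list alone; camera adjusted p = 0.25), with the antiapoptotic gene MCL1 rising from 48.3 ± 1.56 to 76.3 ± 3.75 FPKM. Glycolysis and hypoxia genes rose in 3 and fell in 8 of 24 cases (11 adjusted over the list alone; camera adjusted p = 0.31; median -0.02, mean 0.01). VEGFA, the angiogenic growth factor gene, rose from 6.16 ± 0.509 to 12.003 ± 1.32 FPKM, and the carbonic anhydrase gene CA9 fell from 25.8 ± 0.709 to 12.4 ± 0.461.

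Transcripts of the mitochondrial genome took 15.0%, 14.6% and 15.3% of FPKM in the controls and 13.6%, 13.4% and 9.06% in NaIO3 replicates 1 to 3. Of the 13 transcripts, 3 fell (MT-ATP8, MT-ATP6 and MT-CO3) and 10 did not pass, and 0 passed adjusted over the list alone. MT-CO3, a cytochrome c oxidase subunit gene (chromosome M, 9207 to 9990), went from 3662 ± 105 to 2134 ± 548 FPKM (log2 fold change -0.81, SE 0.19, limma adjusted p = 0.015). With quantile normalization its log2 fold change was -0.08 and the call was lost. The list median of -0.31 (camera adjusted p = 0.022, adjusted p = 0.53 with an estimated correlation) was -0.11 without NaIO3 replicate 3, and the list did not pass with quantile normalization (adjusted p = 0.31) or median centring (0.052). Nuclear-encoded oxidative phosphorylation genes fell in 10 of 29 cases, and none rose (7 adjusted over the list alone; median -0.17, camera adjusted p = 0.0025, adjusted p = 0.20 with an estimated correlation). SDHA, a succinate dehydrogenase subunit gene, fell from 12.9 ± 0.933 to 8.52 ± 0.752 FPKM. ATP5O, of the ATP synthase, fell from 30.1 ± 3.56 to 19.8 ± 4.66 FPKM, a call lost without control replicate 1 or 3 or NaIO3 replicate 2 or 3 (adjusted p 0.059 to 0.080). Ribosomal protein genes of the list fell in 14 of 35 cases, and none rose (7 adjusted over the list alone; median -0.24, camera adjusted p = 3.0e-06, adjusted p = 0.34 with an estimated correlation). Their median was -0.16 without NaIO3 replicate 3. Over all 84 tested ribosomal protein genes and paralogs, a set chosen after values were seen, 32 fell and 1 rose (RPL7L1). RPL22 fell from 78.0 ± 4.76 to 61.5 ± 5.76 FPKM. The RPL22 call was lost without control replicate 1 (adjusted p = 0.055) or NaIO3 replicate 2 (0.051).

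**Figure D3:**
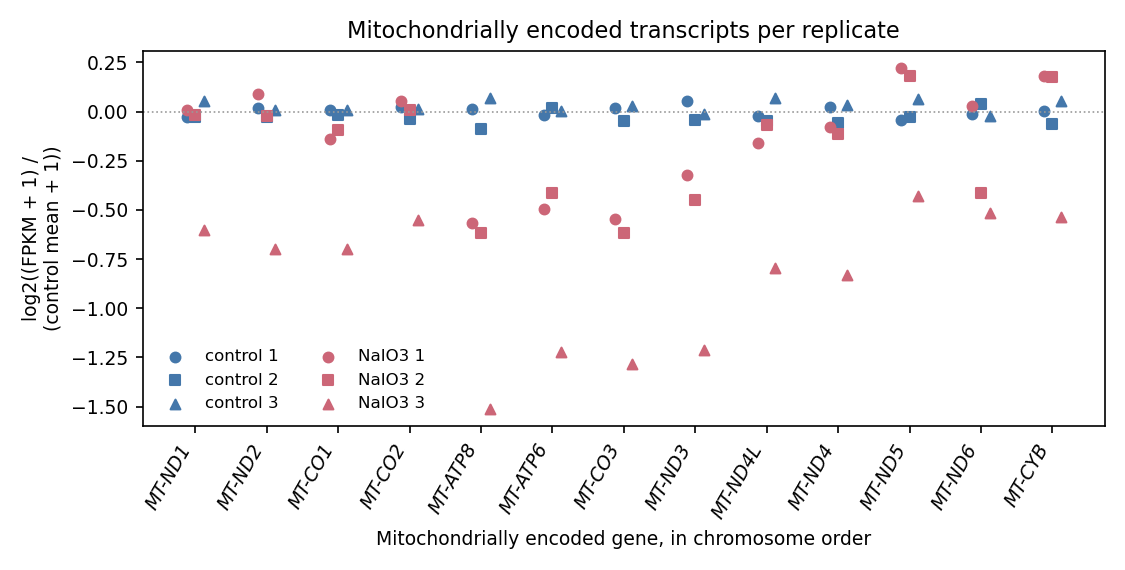
Log2 ratio of FPKM + 1 to the control mean + 1 (vertical axis) for the 13 mitochondrially encoded genes in chromosome order (horizontal axis), with 1 point for each of the 3 control and 3 NaIO3 samples. NaIO3 replicate 3 lies lowest for each gene shown, and 7 genes (MT-CO1, MT-ATP8, MT-ATP6, MT-CO3, MT-ND3, MT-ND4L and MT-ND4) are below every control in all 3 treated samples.

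The largest increases outside the lists, beside HSPA6, included MMP1, which encodes interstitial collagenase, from 0.282 ± 0.113 to 21.5 ± 0.926 FPKM (log2 fold change 4.14, SE 0.08, limma adjusted p = 5.5e-06). The largest decrease among the named genes was that of NPPB, the gene of the natriuretic peptide BNP (chromosome 1, 11917521 to 11918988, hg19), from 40.3 ± 0.624 to 3.89 ± 0.712 FPKM, 10.4-fold lower (limma adjusted p = 2.4e-05). DIO2, which encodes the enzyme that activates thyroid hormone, fell 7.15-fold, from 124 ± 2.22 to 17.4 ± 2.09 FPKM, and HSD17B2, of steroid metabolism, fell from 16.8 ± 0.866 to 2.23 ± 0.328. IL7R fell from 12.97 ± 0.837 to 1.66 ± 1.43 FPKM (0.921, 3.30 and 0.758 in NaIO3 replicates 1 to 3). The log2 fold change of IL7R was -2.51, and -2.92 without NaIO3 replicate 2. DAG1, the dystroglycan gene, stood at 39.3 ± 1.73 FPKM in controls and at 23.8, 2.49 and 2.53 FPKM in NaIO3 replicates 1 to 3 (log2 fold change -2.58, SE 0.73, limma adjusted p = 0.029). Its call was lost on leaving out any sample except NaIO3 replicate 1, with adjusted p from 0.066 to 0.084, and without NaIO3 replicate 1 the log2 fold change was -3.52.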

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

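The alternatives named as chosen after the data were seen are rescaling without mitochondrially encoded transcripts and removal of length, GC and expression trends; the others were set beforehand. The count of genes past the threshold ran from 3906 to 4850 when 1 sample was left out, and calls of at least 2-fold from 312 to 348. With a minimum mean of 5 FPKM, where fewer genes were tested (6653), 3312 genes passed and 1310 were lower. A pseudocount of 0.1 raised the calls of at least 2-fold from 331 to 621, since it shrinks changes of low genes less, and EGR1 then had a log2 fold change of 2.84 in place of 1.79. Under each setting for single genes, all calls shared with the main result had its direction. A gene called under 2 settings that rest largely on the same samples could hardly reverse, so this is no test of the calls. Of 5096 main calls, 5058 were shared with a pseudocount of 0.1. Median centring gave 5084 calls, of which 4370 were shared. The share of higher calls was 58.0%, with 43.8% after median centring, 52.2% with quantile normalization and 64.6% after rescaling to a common sum; the median log2 fold change of all tested genes was 0.04, -0.04, 0.01 and 0.08.

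For single named genes, 855 of the alternative values stayed on their side of the threshold, 24 lost the call and 0 reversed. For lists the corresponding numbers were 476, 29 and 2, and 11 gained a call. Of these, 6 came with fry; the others were ER chaperones with quantile normalization (0.049) and with trends removed (0.027), complement (0.0499) and lysosome (0.047) at a minimum of 5 FPKM, and autophagy with the replicate block (0.046). Camera with an estimated correlation left 4 of 15 lists, and fry, which asks another question, gave 21. Antioxidant enzymes passed with fry upwards, against a median of -0.045, and NF-kB targets, with a median of 0.022, pointed downwards without passing at a minimum of 5 FPKM; the cause was not tested. The calls of p53 targets and extracellular matrix were lost with quantile normalization (adjusted p = 0.069 and 0.070) and with trends removed (0.060 and 0.15), that of NF-kB targets with a pseudocount of 0.1 (0.055), after rescaling to a common sum (0.072) and without mitochondrial transcripts (0.054), and that of interferon response genes with a minimum of 5 FPKM (0.15). The medians were then 0.13 and 0.18 for p53 targets (main 0.19), -0.29 and -0.19 for extracellular matrix (main -0.29) and 0.79 for interferon response genes (main 0.63). For NF-kB targets they were 0.61, 0.47 and 0.43 in the order given (main 0.43). The mitochondrially encoded list had a median of 0.00058 with trends removed (adjusted p = 0.50). Depth is unknown, so its limits could not be set. The replicate number as a block gave 4461 genes and 16 lists. Deviations of same-numbered samples from their group means correlated at -0.0048, -0.027 and -0.034. No sample of either group correlated best with its own number, but the highest value of any pair was 0.052 (control replicate 2 with NaIO3 replicate 3). No pairing by number was detected, and values this near 0 cannot exclude one. Analyses of raw or recovered read counts were not run, since the values are FPKM.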

Other observations

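The lists and tests here were chosen after gene values were seen, except the counts over other splits of the samples; the bounds for the mitochondrial, mitosis and the 2 separate trend tests were also set after their values were known. Fatty acid synthesis genes fell in 7 of 15 cases and rose in 2 (9 past the threshold adjusted over the list alone). FASN, the fatty acid synthase gene, went from 55.3 ± 5.08 to 29.3 ± 4.27 FPKM and the desaturase gene FADS2 from 37.2 ± 2.04 to 17.1 ± 0.358 (SD, n = 3), whereas ME1 rose from 13.5 ± 0.588 to 24.8 ± 0.549. Proteasome subunit genes in the list, which holds PSMB1 to PSMB7 of the PSMB genes, rose in 18 of 31 cases, and none fell (18 adjusted over the list alone). PSMB8, PSMB9 and PSMB10, which encode the immunoproteasome subunits and lie outside the list, fell, and over all 37 tested genes with PSMA to PSMD symbols 18 rose and 3 fell. PSMD12 went from 17.0 ± 0.816 to 28.1 ± 2.04 FPKM. Feedback and output genes of the ERK pathway rose in 14 of 17 cases, and 1, CCND1, fell (16 adjusted over the list alone). Beside feedback regulators the list holds output genes such as ETV1, ETV4, ETV5, FOSL1 and CCND1. In all, 5 members also stand in the lists fixed beforehand. SPRY4 rose from 0.380 ± 0.033 to 3.47 ± 0.307 FPKM and ETV5 from 5.68 ± 0.302 to 19.2 ± 1.26. Keratin genes, of which 2 are also RPE markers, fell in 4 of 5 cases (4 adjusted over the list alone), including KRT80 from 145 ± 33.7 to 28.8 ± 6.35 FPKM. The list left out other keratins: over all 9 tested genes with KRT symbols 5 fell and 2 rose (KRT31 and KRT34), and that family did not pass (adjusted p = 0.16). Targets of YAP and TEAD rose in 5 and fell in 7 of 16 cases (12 adjusted over the list alone; camera adjusted p = 0.32).

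Camera adjusted p-values over these 6 lists were 0.0088 for fatty acid synthesis, 0.00030 for proteasome subunits, 8.1e-06 for ERK feedback and output genes and 0.00063 for keratins. These 4 calls were lost with an estimated correlation, with adjusted p = 0.085, 0.12, 0.064 and 0.064 in that order. Of 200 gene families defined by the letters that open the symbol (at least 8 tested members), 10 passed camera with the preset correlation and 0 with an estimated one. Collagen genes fell in 10 of 16 cases (median -0.36, adjusted p = 0.0019), and annexin genes fell in 8 of 12 and rose in 1 (median -0.43, adjusted p = 0.012); with an estimated correlation both had adjusted p = 0.76.

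One hypothesis was that the fall of cholesterol synthesis transcripts belongs to a fall of the wider SREBP programme, which includes fatty acid synthesis. The fatty acid list had a median log2 fold change of -0.27 and passed camera downwards, in line with that hypothesis, although the call was lost with an estimated correlation. A second hypothesis was an excess of sterol in the cells, which would raise LXR targets. Of 8 tested LXR targets, 4 rose and none fell (4 adjusted over the list alone), ABCA1 from 0.616 ± 0.0953 to 2.99 ± 0.051 FPKM. Their median was 0.21, and the list did not pass (camera adjusted p = 0.28, adjusted p = 0.34 with an estimated correlation), so this stays open. For heat shock proteins, 1 hypothesis was a response to misfolded protein that includes the proteasome, which would raise proteasome subunits as a list. Those subunits rose as a list (median 0.30), again with the call lost with an estimated correlation. Their rise does not show what raised them, so this hypothesis stays open. A smaller share of cycling cells, with no shift between phases of the cycle, would lower replication and mitosis transcripts together. The mitosis list had a median of 0.21, and its lowest member, MKI67, stood at -0.44, against -1.01 for replication, which argues against that as the whole cause of the fall of replication transcripts. The mitosis median was lower, 0.14, without NaIO3 replicate 3 and 0.12 with trends removed, but still above 0. A shift of cells between phases could not be assessed from these values.

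In chromosome order MT-ATP8, MT-ATP6, MT-CO3 and MT-ND3 follow each other (8366 to 10404), and they had the 4 largest decreases of the 13, with log2 fold changes of -0.90, -0.71, -0.81 and -0.66; MT-ND3 did not pass (adjusted p = 0.051). A source in NaIO3 replicate 3 alone was tested by leaving it out. Of MT-ATP8, MT-ATP6 and MT-CO3, 3 still fell, which argues against it for these genes, and in the run of 4 the weakest value was -0.38 against -0.19 for the lowest of the rest. That weakest value is MT-ND3, which then passed, so the argument holds for it too. Of the other 9 transcripts 1 then fell (MT-CO1) and 2 rose (MT-ND5 and MT-CYB), with a median of -0.0036, so for them an effect of that sample and one of NaIO3 cannot be told apart with 2 remaining samples. In all 3 treated samples 7 genes lay below every control, namely the run of 4, MT-CO1, MT-ND4L and MT-ND4.

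Of ribosomal protein transcripts 14 of 35 fell and of oxidative phosphorylation transcripts 10 of 29, and both list calls were lost with an estimated correlation (adjusted p = 0.34 and adjusted p = 0.20 with an estimated correlation). Under 4 other scalings the higher of their medians was -0.12, which argues against scaling as the whole cause. With trends in length, GC content and mean level removed, the medians were -0.094 for ribosomal proteins and -0.17 for oxidative phosphorylation, from -0.24 and -0.17, and the second list still passed with the preset correlation (adjusted p = 0.0033), so a trend is unlikely to be the whole cause of that preset call. The ribosomal call ended (adjusted p = 0.052) because its fold shrank, but with trends fitted without 208 ribosomal and mitochondrial genes its median was -0.14 and it passed (adjusted p = 0.011). For ribosomal proteins, a trend and an effect of NaIO3 cannot be told apart, because the 2 ways of fitting the trend gave different calls.

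In 229 genes, 1 sample stood at least 2-fold from both others of its group on the log2(FPKM + 1) scale while those agreed within 1.2-fold, among them DAG1 and IL7R. They made up 3.02% of the calls of at least 2-fold (10 genes). No single sample stood apart in more than 49 of the 229 genes (21.4%). The highest share was 18.1% of 271 cases when the 42 genes with a sample apart in both groups count once for each group. These genes therefore did not gather in 1 library. Smaller shifts across many genes would escape this count, so it cannot exclude a library of lower quality. Mitochondrial transcripts took 9.06% of FPKM in NaIO3 replicate 3, against 13.6% and 13.4% in NaIO3 replicates 1 and 2. Genes with several transcripts had 0.78 times the share found in genes with 1 transcript at matched levels (0.50 to 1.38 over 1000 resamples of genes). A 2-fold excess lay outside that range, but a smaller excess did not. Only 18 of 659 genes with 1 transcript stood apart, so the division of reads among transcripts stays open as a partial source. Of the 229 genes, 43.2% overlapped another gene of the table, against 28.1% of the others, a ratio of 1.54 (1.31 to 1.76). Reads of overlapping genes therefore stay open as a partial source.

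With 10 splits of the 6 samples into 3 and 3, a share under 0.05 cannot be reached. The real split gave 5096 genes, 331 genes changed at least 2-fold and 15 lists, and it was the 1 split with a result as large in each case. The highest of the other splits was 3 genes, 3 genes and 10 lists, and each of them passed at least 7 lists. Each of those splits puts treated and control samples in both groups. The treatment difference then adds to the spread within groups, so few gene calls were to be expected. Those splits are therefore no measure of chance.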
